A study of Danio rerio with 2 samples.

How the data were processed

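The study profiled single cells of the zebrafish caudal hematopoietic tissue, the tail region in which blood stem and progenitor cells multiply in the larva. Per the labels, 2 samples were made, 1 at 3.5 and 1 at 4.5 days post fertilization, from fish carrying a red kdrl reporter of endothelial cells and a green CD41 reporter of thrombocytes and progenitors. Dissociated tails were sorted into 50000 cells of each reporter plus double negative cells, which can affect the shares of cell types. The labels name the 10x Genomics single cell 3′ kit, version 2, and say that a library of an earlier stage from another series was analysed again; 1 of the 3 barcode sets described below may be that library, to which this sort need not apply.

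The authors deposited 1 table of raw counts, with 18808 genes in rows and 28777 cell barcodes in columns. Every value was a whole number of at least 0. The submitters' processing notes name UMI-tools, STAR and the genome build GRCz10, with no versions and no roles, and the limits applied to cells are not given in the sources used here. Column names end in 1 of 3 suffixes, which split the cells into 3 barcode sets of 8725, 11823 and 8229 cells. No label ties a suffix to an age, so no column was given to a sample, and the planned comparisons of 4.5 with 3.5 days could not be run. The table was treated as 1 pooled sample, as had been fixed for this case before the data were examined. Values of the barcode sets are printed side by side, without a test and without reading an age into any set. Across the sets, 369 barcode sequences recurred.

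The largest number of genes in a cell was 3499, 2998 and 2979 in sets 1, 2 and 3, and the highest mitochondrial percent was 18.0, 20.0 and 15.0, so the deposited cells had the look of cells already filtered with limits of each set. Cells were kept with at least 500 unique molecular identifiers (UMIs), at least 200 genes and at most 10% mitochondrial counts. All deposited cells met the first pair of limits, and 954 exceeded the last. A gene named only by a sequence identifier held 0.498% of counts and was kept as a gene without being counted as mitochondrial. Copies of globin and heat shock genes, and 58 genes named as 1 of many, share sequence, so the division of counts between copies is uncertain. Antisense and overlapping genes are uncertain too, as the counting rules are not given in the sources used here.

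Doublets were first called with Scrublet and its automatic limit, which marked almost no cells in sets 2 and 3. Its procedure was then rewritten with exact neighbours, 2 simulated doublets per cell and 1 score limit of 0.25, which was chosen after the scores were seen. It marked 516 cells (1.79%), with 157, 244 and 115 in sets 1, 2 and 3. After all filters 27318 cells were kept and 1459 left out.

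Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes, ranked within sets, gave 30 principal components, a graph of 15 nearest neighbours weighted by shared neighbours, and 39 Leiden clusters at resolution 1, without batch correction. Clusters were named from marker lists fixed before the data were examined, by the mean log2 fold of a class's markers over the median cluster, with an offset of 10 CPM and negative values set to 0. A name needed at least 3 detected markers (10% of cells, log2 fold of 1). A cluster stayed unnamed if another class had more markers than its own among its 10 leading genes (found in at least 20% of cells), or if its median count was under 0.333 of its set's with no own marker among them.

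The scoring rule was set after clusters were seen, and 3 of its parts were chosen with their effect in view. The first contrast, against all other cells, left every progenitor cluster unnamed and was replaced by the median cluster. A looser rule on markers of other classes was then used for a time, because the stricter one left clusters 6 and 7 without a name. It was given up when other clusterings of the same cells did not give the share of progenitor-like cells it had given, and the stricter rule was restored for all values reported. A minimum score of 0.7 was set after the scores had been seen. Results under the discarded choices are in the closing section.

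Counts were summed over the cells of each class and expressed as CPM of the sum, with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals. Both cover counting error only, since cells of 1 library are not replicates; no p-value was computed. A gene counted as led by a class if the class had the highest CPM among classes of at least 50 cells, with at least 20 CPM and 10 UMIs. Gene lists were compared between classes in place of ages, a choice made after the files were seen. For each gene with at least 10 UMIs, the log2 ratio of a class's CPM to the mean of the other classes of its kind (hematopoietic or not) was taken with the offset of 10 CPM, which understates changes of low genes. The median over a list was set beside 10000 random lists of the same size matched on mean expression, as a description of these libraries. Of the 8 lists compared in this way, 5 had no gene in common with the naming markers, and the others had 3, 1 and 1.

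For shares of cells with G2/M transcripts, each cell was thinned to 1000 UMIs, which left out 785 cells (110, 502 and 173 in sets 1, 2 and 3), and at least 2 G2/M UMIs were required. Progenitor-like and endothelial-like cells were clustered again for subclusters. Alternatives covered cell filters, clustering resolution, separate clustering of sets, doublets, naming rules, thinning, the omission of single barcode sets or of globin counts, and scaling, including TMM factors from edgeR 4.0.16 in R 4.3.3. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

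The steps were tested on simulated data. Of 4500 simulated cells of the 15 named classes, over 18808 genes, 99.8% were given their class, with 97% in the lowest class; such cells lack the overlap of real ones. In class sums simulated for the progenitor-like class against the other hematopoietic classes over 15946 genes, 100 genes made 2-fold higher had a median log2 ratio of 0.76, where the offset allows 0.75. Another 100 genes made 4-fold higher had 1.67, where it allows 1.66.

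Named genes follow the rule fixed before the data were examined for a table without sample labels: only classes and the genes they carry are described, with members of the fixed lists that had the highest CPM in a class or stood at the ends of their list. The genes il4, il13 and hmgb2a and hmgb2b as a pair were singled out after their values were seen.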

Results

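Single-cell transcriptomes were collected from the caudal hematopoietic tissue of zebrafish at 3.5 and 4.5 days post fertilization, with 1 sample per age and no replicates. The tissue receives blood stem and progenitor cells from the dorsal aorta and holds them beside a venous plexus, stromal cells and macrophages. Cells had been sorted as 50000 kdrl-positive endothelial cells, 50000 CD41-positive cells and double negative cells, to give an atlas of the blood cells and of their surroundings. The table held 276291982 counts over 28777 cells and 18808 genes, with a median of 8532 counts and 1355 genes per cell. Its 3 barcode sets held 91589999, 116503176 and 68198807 counts, with medians of 10665, 8956 and 6743 counts per cell. Per the labels, a library of an earlier stage from another series was analysed again, so 1 of the 3 sets may be that library and not all cells need be of these ages. Which set belongs to which age or library is not given in the sources used here, so the cells are described as 1 pooled sample and no change with age is reported.

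Of 27318 kept cells, 18079 (66.2%, interval 65.6 to 66.7) were in hematopoietic classes, and erythroid-like cells were the most numerous class with 7260 cells (26.6%, 26.1 to 27.1). Neutrophil-like cells, which carry granule proteases and lysozyme, followed with 3272 cells (12%), then progenitor-like cells with 3056 (11.2%, 10.8 to 11.6). Lymphoid-like cells numbered 2026 (7.42%), macrophage-like cells 1433 (5.25%) and thrombocyte-like cells, the nucleated platelet equivalent of fish, 1032 (3.78%). With fold over all other cells used in naming, 42.5% were hematopoietic, 14.0% erythroid-like, 0% progenitor-like and 39.9% unnamed. The thrombocyte-like share was 1.83% at Leiden resolution 2 and 1.1% without a filter on cells. Classes were named from marker genes, so those markers are not findings of their own. Some names rest on few markers. Lymphoid-like clusters 4 and 27 had 4 and 5 of 16 measured markers detected, with scores of 1.29 and 1.12. No lymphoid marker was among the leading genes of cluster 27. Progenitor-like clusters 1 and 11 had 4 and 5 of 10 measured markers detected, with scores of 1.08 and 1.195. Among hematopoietic cells alone, erythroid-like cells were 40.2% and progenitor-like cells 16.9%.

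Non-blood classes were led by neuronal-like cells (2680, 9.81%), with 740 epidermal-like (2.71%), 602 mesenchymal-like (2.2%), 454 neural progenitor or glial-like (1.66%) and 324 notochord or cartilage-like cells (1.19%). Mucus-secreting-like cells (186, 0.681%), intestinal or hepatic-like cells (170, 0.622%) and skeletal muscle-like cells (61, 0.223%) were fewer. Only 125 cells were endothelial-like (0.458%, 0.381 to 0.545), although the sort described for the 2 samples had included 50000 kdrl-positive cells; whether it applies to all 3 sets is not given in the sources used here. With each barcode set clustered on its own, shares were 0.198% endothelial-like, 0.106% mucus-secreting-like, 0.392% intestinal or hepatic-like and 1.45% mesenchymal-like. Sorting can affect such shares, which are not shares of the tissue, and 3897 cells (14.3%) in 5 clusters had no name.

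The 3 barcode sets differed in their makeup. Erythroid-like cells were 14.5%, 22.7% and 44.6% of sets 1, 2 and 3, and progenitor-like cells were 16.9%, 11.8% and 4.28%. Lymphoid-like cells were 1.82% of set 1 against 9.25% and 10.8% of sets 2 and 3, and epidermal-like cells were 6.15% of set 1 against 1.38% and 0.915%. Unnamed cells were 16.5%, 14.8% and 11% of the sets. Different clusters held the erythroid-like cells of the sets: cluster 3 had 776, 989 and 95 cells in sets 1, 2 and 3, and cluster 2 had 174, 161 and 1641. The erythroid-like cluster 5 had 121, 786 and 796 cells in the sets, and cluster 10 had 138, 426 and 748. Their marker scores were 0.91 and 1.11, and myb, a progenitor marker, was among the leading genes of both. The erythroid-like and progenitor-like shares of the sets therefore depend on how clusters 5 and 10 are named. Clusters 6 and 7, with 1663 and 1473 cells, matched the progenitor markers best but had tcf15, a mesenchymal marker, among their leading genes, so they stayed unnamed; with them the progenitor-like share would be 22.7%.

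**Figure D1:**
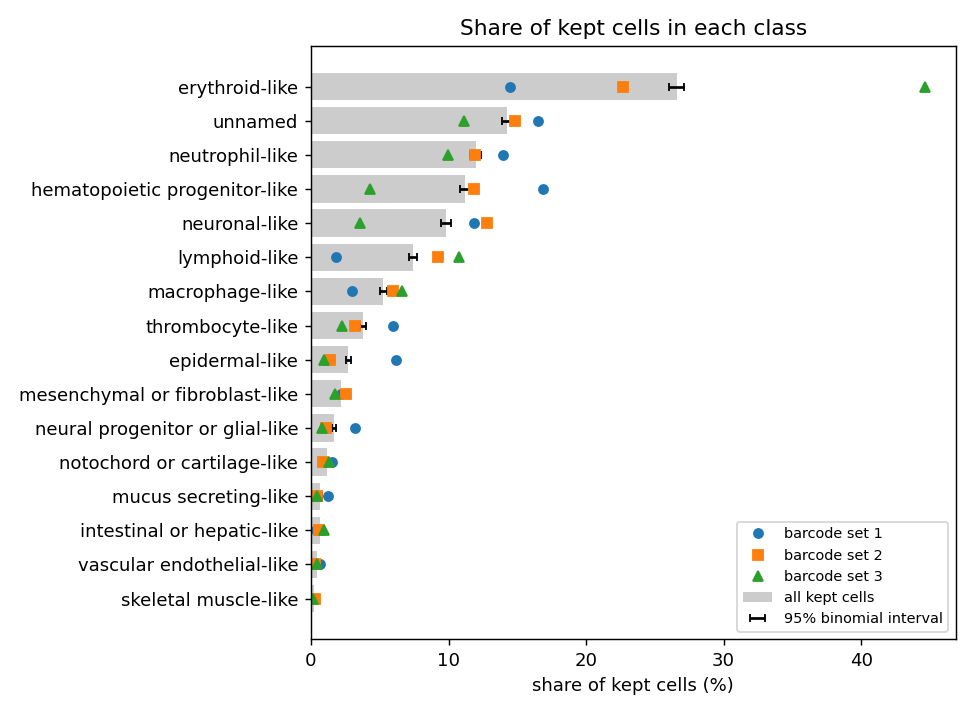
Share of kept cells (%) in each class, as bars for all kept cells with the exact 95% binomial interval and as points for the 3 barcode sets. Erythroid-like cells range from 14.5% to 44.6% of a set, and endothelial-like cells are 0.458% of all kept cells.

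The next question was which cells carry the signals of the tissue. Of the ligand list, 31 genes reached 20 CPM and 10 UMIs in a class, and mesenchymal-like cells led 9 of them. These included ccl25b, the chemokine ligand of ccr9 receptors, with 174 CPM (157 to 193) against 18.6 CPM in the next class, and fgf10a with 115 CPM (101 to 130). The bone morphogenetic protein genes bmp4 (111 CPM) and bmp2b (89.7 CPM) and the Wnt enhancer rspo3 (34.6 CPM) were also highest there. Endothelial-like cells led 6 ligands, among them the Notch ligand dll4 with 384 CPM (314 to 465) and cxcl12a, a retention signal for blood progenitors, with 177 CPM (131 to 235) against 92.5 CPM in mesenchymal-like cells, of which it is a naming marker. Without set 2, cxcl12a had 95.5 CPM (58.3 to 148) in endothelial-like cells. The median class had 0.672 CPM of dll4 and 0.486 CPM of cxcl12a.

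Macrophage-like cells had 728 CPM (715 to 742) of csf3b, a granulocyte colony-stimulating factor gene, against 65.9 CPM in the next class. Neutrophil-like cells had 542 CPM (534 to 551) of il34, a ligand of the macrophage receptor csf1r, against 19.9 CPM in the next. Thrombocyte-like cells led apln (501 CPM, 486 to 517), angpt1, an activating ligand of the endothelial receptor tek (66.4 CPM, 61.0 to 72.2), and vegfc (43.1 CPM, with 36.9 CPM in endothelial-like cells inside counting error). For vegfc, cluster 13 had 22.7 CPM and cluster 29 had 225 CPM; the class had 91.2 CPM without set 1 and 23.2 CPM without set 2, where endothelial-like cells led. Progenitor-like cells were next for apln and angpt1, with 102 and 13.3 CPM.

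Cells outside blood and vessels led the 3 ligands of highest CPM. The midkine genes mdka and mdkb had 2699 and 1009 CPM in neural progenitor-like cells, and mdka had 1408 CPM in epidermal-like cells. In sets 1, 2 and 3, the level of mdka in this neural progenitor or glial-like class was 3624, 1165 and 547 CPM. The makeup of the class differed between the sets. Cluster 22, with mdka among its leading genes, had 262, 66 and 25 cells in sets 1, 2 and 3. Cluster 37, with mbpa and plp1b among its leading genes, had 4, 56 and 41. Epidermal-like cells had 1158 CPM of cxcl18b and 284 CPM of cxcl8a, both neutrophil attractants, against 458 CPM in mesenchymal-like and 75.9 CPM in macrophage-like cells; cxcl8a had 589 CPM without set 1. The stem cell factor gene kitlga had 37.1 CPM (25.9 to 51.7) in mucus-secreting-like cells, a class whose size depended on the clustering, and 36.1 CPM in notochord-like cells, inside counting error. In mucus-secreting-like cells it had 12.7 CPM in set 1 and 92.1 CPM in set 2, and 18.5 CPM without set 2; notochord-like cells led it without set 2 and without set 3. Notochord-like cells had 539 CPM of thbs1b, a thrombocyte naming marker, and thrombocyte-like cells had 345 CPM.

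**Figure D2:**
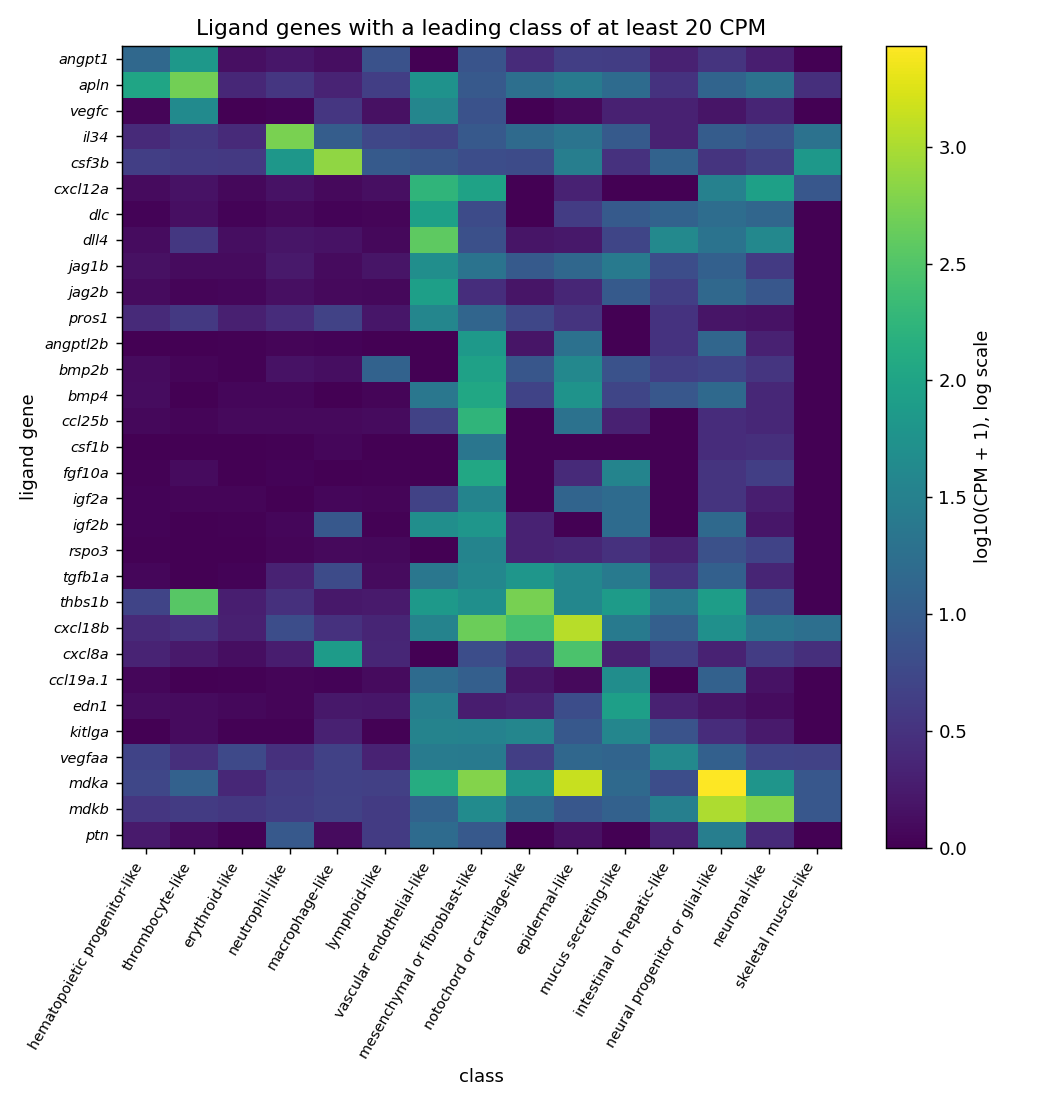
Ligand genes with a leading class of at least 20 CPM (rows) in each class (columns), coloured by log10 of CPM plus 1. Dark cells are at or near 0; csf3b stands out in macrophage-like cells with 728 CPM and il34 in neutrophil-like cells with 542 CPM.

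Neutrophil-like cells led cxcr4b, the receptor of cxcl12 (571 CPM, 563 to 580), with 519 CPM in macrophage-like cells, and the integrin gene itgb2 (130 CPM) and selplg, a selectin ligand (44.5 CPM). Endothelial-like cells led the paralog cxcr4a (521 CPM, 438 to 614, but 190.0 CPM, 125 to 276, without set 1) and ackr3b, a scavenger receptor of cxcl12 (321 CPM, 257 to 396), which had 205 CPM there without set 3 and 164 CPM in mesenchymal-like cells. Lymphoid-like cells led ccr9a (1123 CPM), which was also one of their naming markers, and macrophage-like cells had 555 CPM. Neural progenitor-like cells led notch3 (508, 46.4 and 45.1 CPM in sets 1, 2 and 3) and notch1a (193, 42.2 and 25.8 CPM), which endothelial-like cells led without set 1. As given above, the neural progenitor or glial-like class was made up of different clusters in the sets. In all, 16 receptor genes met the limits.

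Of 30 adhesion and matrix genes, mesenchymal-like cells led 17, of which 9 were not among the markers that named them. Examples outside the markers were vcanb (485 CPM, 322 CPM without set 1, with 389 CPM in epidermal-like cells over all sets), cdh11 (124 CPM, 80.2 CPM without set 1) and mmp14a (69.2 CPM). Endothelial-like cells led 5, including timp2b (377 CPM, 307 to 457), the basement membrane genes lama4 (88.6 CPM, 49.2 CPM without set 1) and col4a2 (55.4 CPM), and their markers sele, which thrombocyte-like cells led without set 1, and cdh5. Notochord-like cells led sparc with 8401 CPM. Epidermal-like cells had nearly as much col1a1a (5224 CPM) as mesenchymal-like cells (5640 CPM), and led it without set 2. The fin fold genes and1 and and2 were among the leading genes of both cluster 16, the whole mesenchymal-like class, and cluster 20 of the epidermal-like class, which also had and3.

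Over all 77 genes, 69 had the same leading class when cells were thinned to 1000 UMIs and ranked by the share of cells with a UMI. The leading class had a CPM interval apart from that of the next class for 23 of 31 ligands, 12 of 16 receptors and 23 of 30 adhesion genes. It led in every set compared for 22 ligands, 13 receptors and 22 adhesion genes, and mesenchymal-like cells did so for 5 of their 9 ligands and 12 of their 17 adhesion genes. With sets 1, 2 and 3 left out in turn, a check chosen after the data were seen, 70, 70 and 74 of the 77 genes had the same leading class, and 27 genes moved by over 1.5 times with at least 1 set left out. Endothelial-like cells reached 50 cells in set 1 only, so sets cannot be compared for them one by one. The counts of genes led in every set compared include 4 ligands, 4 receptors and 5 adhesion genes of endothelial-like cells, which rest on set 1 alone. Classes under 50 cells in a set were not ranked in it, so in sets 2 and 3 no gene was set against endothelial-like cells.

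Gene programs were compared between classes. Progenitor-like cells had more transcripts of ribosome biogenesis genes than the mean of the other hematopoietic classes. All 34 members were higher, with a median log2 ratio of 1.13, at percentile 100 of 10000 random lists. In sets 1, 2 and 3 the median was 1.35, 0.89 and 0.90. The contrast is with whole classes and not with every cluster in them. Without globin counts, these genes summed to 7047, 7829 and 822 CPM in erythroid-like clusters 5, 10 and 3, against 4804 to 13028 CPM over the progenitor-like subclusters with all counts. In progenitor-like cells, the nucleolar genes ncl, npm1a and fbl had 1018, 886 and 524 CPM. The next class was lymphoid-like for ncl (613 CPM) and erythroid-like for npm1a and fbl (439 and 285 CPM). Genes of scavenging and lysosomes were lower in all 24 members (−1.13, percentile 0), as were 34 of 35 stress genes (−0.80), 24 of 27 interferon and inflammation genes (−0.42) and 18 of 22 glycolysis genes (−0.48). The median of 3020 genes above 20 CPM was itself 0.15 in this class, so the 0.16 of 36 oxidative phosphorylation genes (percentile 49.8) did not stand apart. Differences between these classes have no replicate check.

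Macrophage-like cells were higher in 23 of 24 lysosomal genes (1.44, percentile 100), led by the cathepsin gene ctss2.2 (4.84), which is a naming marker, and in 30 of 35 stress genes (0.63). The stress median of this class was 1.17, 0.81 and 0.13 in sets 1, 2 and 3, and 0.40 without a filter on cells. The class joined cluster 12, with 70, 328 and 391 cells in the sets, and cluster 15, with 180, 325 and 139. Neutrophil-like cells were higher in 18 of 22 glycolysis genes (0.74, percentile 100), with the enzyme gene gapdh at 6.56, and lower in all 34 ribosome biogenesis genes (−1.36, percentile 0). Erythroid-like cells were lower in 21 of 22 glycolysis genes (−0.92, percentile 0). Their ribosome biogenesis median differed in sign between sets, with −0.57, 0.37 and 0.46 in sets 1, 2 and 3. The makeup of the class differed too. Cluster 3, in which globins took most counts, held 776 of 1214, 989 of 2487 and 95 of 3559 erythroid-like cells of the sets. Over all sets the ribosome biogenesis median was 0.09 with class totals and 0.62 with TMM scaling, where the median gene stood at −0.42 and 0.04.

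Endothelial-like cells were higher than other non-hematopoietic classes in 18 of 24 lysosomal genes (0.80, percentile 100), led by the protease gene lgmn at 4.13. The lysosomal median was 0.14 in set 1, the only set with at least 50 endothelial-like cells, and 27 of the 33 cells of the subcluster with the highest lysosomal sum came from set 2. They were also higher in 29 of 35 stress genes (0.68), with the flow-responsive gene klf2a at 3.26. The stress median was 0.29 in set 1, and 31 of the 45 cells of the subcluster with the highest stress sum came from set 3. Stress genes summed to 32135 CPM in this class, the highest of all classes, against 26384 CPM in mesenchymal-like cells, and in set 1 to 23082 CPM against 20735 CPM. Over all sets the stress median was 0.36 with every cell weighted equally and 0.39 with TMM scaling.

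Transcripts of dividing cells were compared next. The 2 clusters of thrombocyte-like cells differed in direction. Against other hematopoietic classes, cluster 13 was higher in 31 of 31 G2/M genes (median 1.79) and 26 of 26 S phase genes (1.0), whereas cluster 29 was higher in 2 of 31 (−0.68) and 2 of 26 (−1.03). Over the whole class the medians were 1.65 and 0.89 (percentile 100 for both), with ccna2, a cyclin, at 2.22. Without a filter on cells they were 0.93 and −0.57, and at Leiden resolution 2 the S phase median was 0.22. Lymphoid-like cells were lower in 30 of 31 G2/M genes (−1.31) and in all 26 S phase genes (−0.84). Within sets 1, 2 and 3 their medians were −1.62, −0.79 and −0.93 for G2/M, and −0.36, −0.56 and −0.66 for S phase. At Leiden resolution 2 the pooled G2/M median of this class turned to 0.13 and its S phase median was −0.25. Progenitor-like cells were at 0.22 for S phase (percentile 83.4) and 0.19 for G2/M (percentile 93.7), close to the 0.15 of the median gene. Within sets, the S phase values were 0.49, −0.11 and 0.01 and the G2/M values 0.45, −0.02 and −0.01 in sets 1, 2 and 3. At Leiden resolution 2 the pooled values were 0.42 for S phase and −0.26 for G2/M. Without a filter on cells the S phase median was 0.58.

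By the planned measure, 61.5% (59.7 to 63.2) of progenitor-like cells had at least 2 G2/M UMIs after thinning to 1000 UMIs, and 75.5% (72.8 to 78.1) of thrombocyte-like cells. The share was 65.6% in neural progenitor-like, 58.7% in mucus-secreting-like, 46.0% in erythroid-like, 39.0% in neutrophil-like and 29.6% in lymphoid-like cells. The order of the last 3 classes differed between sets, with 30.6%, 28.1% and 63.8% in erythroid-like, 57.8%, 26.7% and 31.4% in neutrophil-like and 58.8%, 24.9% and 30.0% in lymphoid-like cells of sets 1, 2 and 3. Of classes taken as cells that should not divide, neuronal-like cells had 26.6% (median depth 1842 counts) and skeletal muscle-like cells 3.28% (7747 counts). The neuronal-like share was 55.8% in cluster 23, 31.7% in cluster 28 and 28.6% in cluster 18. It was 13.8% in cluster 9 and 12.96% in cluster 36. Whether cluster 23 holds dividing cells was not tested, so the class share may overstate false calls. Progenitor-like cells had a median depth of 13730.5 counts, and 97.7% of them passed without thinning. The chromatin genes hmgb2a and hmgb2b of the list had 676 and 765 CPM in neuronal-like cells. Without this pair, a choice made after these values were seen, the shares were 22.9% (21.4 to 24.4) in progenitor-like, 39.1% in thrombocyte-like, 14.6% in erythroid-like, 3.76% in lymphoid-like and 1.97% in neuronal-like cells. All other shares given by class, cluster or barcode set are with the pair in the list, and their order may rest on it.

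The planned share in progenitor-like cells was 84.8%, 38.5% and 52.1% in sets 1, 2 and 3, and in thrombocyte-like cells 96.6%, 51.1% and 63.8%. Of the progenitor-like cells of set 1, cluster 11 held 713 and cluster 1 held 704, whereas of those of set 2 they held 231 and 1067. Cluster 11 had 96.9% of cells past the limit and cluster 1 had 43.0%. Within cluster 1 the share was 70.9%, 26.5% and 33.9% in the sets. The thrombocyte-like class joined cluster 13, with 481, 162 and 113 cells in the sets and a share of 89.1% (86.7 to 91.2), and cluster 29, with 19, 188 and 69 cells and a share of 37.3% (31.5 to 43.4). Cluster 13 had the blood gene blf and the erythroid gene rhag among its leading genes, beside apln and thbs1b. The genes blf, rhag, hdr and pmp22b were leading genes both of this cluster and of progenitor-like clusters 1 and 11. Cluster 13 may therefore lie close to the progenitor-like class.

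**Figure D3:**
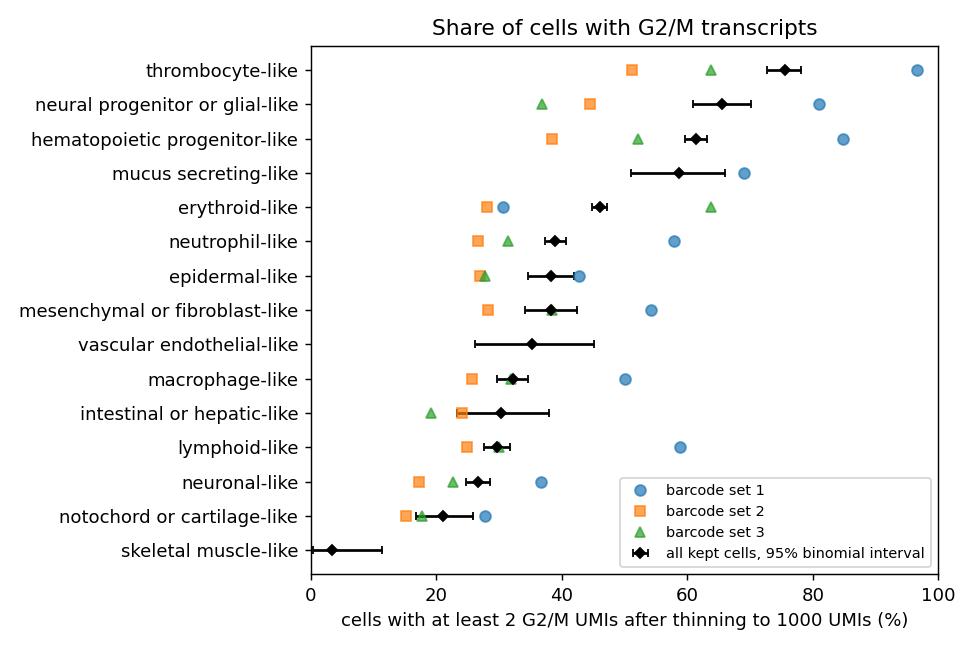
Percent of cells with at least 2 G2/M UMIs after thinning to 1000 UMIs in each class, for all kept cells (diamonds, exact 95% binomial interval) and for each barcode set with at least 50 cells. With hmgb2a and hmgb2b in the list, as plotted, thrombocyte-like cells are highest at 75.5%, and set 1 lies above set 2 in each class plotted for both.

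Inside the progenitor-like class, 14 subclusters were found. Erythroid differentiation genes summed to 2215 and 2074 CPM in subclusters 10 and 13, which had slc4a1a, a red cell anion exchanger, among their leading genes, against 392 CPM in subcluster 1. Lymphoid priming genes summed to 1886 CPM in subcluster 14 (15 cells) and 886 CPM in subcluster 11, against 186 CPM in subcluster 2. Genes of progenitor factors were highest in subcluster 9 with 6274 CPM, where interferon and inflammation genes summed to 5923 CPM. Both lists contain cebpb, so these sums are not independent. Subcluster 9 also had the highest stress sum of the 14 (7981 CPM). Its leading genes included ier2b and jun of the stress list and nfkbiab and nfkbiaa of the inflammation list. It held 860048 counts in 158 cells, against 6171113 counts in 492 cells of subcluster 1. Over whole classes the progenitor factors summed to 2415 CPM in progenitor-like cells and to more in neutrophil-like (5795 CPM), macrophage-like (4359.6 CPM), lymphoid-like (4149 CPM), epidermal-like (3277 CPM) and endothelial-like cells (3213 CPM). Myeloid granule genes ranged from 299.5 to 767 CPM over the subclusters, against 175980 CPM in neutrophil-like cells. In 9 subclusters with 1743 of the 3056 cells, over 90% of cells came from 1 barcode set, so a subcluster may be a library and not a state; sizes are not compared.

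Endothelial-like cells formed 4 subclusters of 45, 35, 33 and 12 cells. Arterial genes summed to 3074 and 2417 CPM in subclusters 1 and 2 and to 381 and 766 CPM in subclusters 3 and 4. Venous and sinusoidal genes had the opposite order, with 2624 and 3074 CPM against 11712 and 10794 CPM. Subcluster 3 was also highest in lysosomal genes (14520 CPM) and lymphatic genes (1364 CPM), and lyve1b, a receptor of venous and lymphatic endothelium, was among its leading genes. The venous list shares lyve1b, mrc1a and flt4 with the lymphatic list and ctsla, cd36 and lamp2 with the lysosomal list. Sums over these lists are therefore not independent. Stress genes summed to 60524 CPM in subcluster 1, against 9867 CPM in subcluster 3. Subclusters 1 to 3 took 68.9%, 82.9% and 81.8% of their cells from 1 barcode set, and subcluster 4 took 91.7%.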

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

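The looser naming rule, the contrast against all other cells, the absence of a minimum score, the doublet limit of 0.2, the G2/M list without hmgb2a and hmgb2b, and for gene lists Leiden resolution 2, no filter on cells, single thrombocyte-like clusters, leaving out each barcode set, and the omission of globin counts were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the columns carry no sample and each age has 1 sample. The planned comparisons of ages, with their scaling alternatives, were not run as written; the scaling alternatives were applied to the comparison of classes. In all, 442 values stayed within their counting interval, or for a list within the 95% interval of its median, 217 moved beyond it and 5 list medians changed sign. The cause of a move was not tested unless the alternative's own construction gives it.

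The share of progenitor-like cells depended on naming more than on filters or resolution. Over the planned clusterings and filters it lay between 10.3% and 13.7%. With the looser rule, which names clusters 6 and 7, shares were 22.7% progenitor-like (29.9%, 23.7% and 13.6% of sets 1, 2 and 3), 2.79% unnamed and 77.7% all hematopoietic; unnamed cells were then 3.58%, 2.93% and 1.76% of sets 1, 2 and 3. With fold over all other cells, shares were 14.0% erythroid-like, 0% progenitor-like, 6.70% neuronal-like, 39.9% unnamed and 42.5% all hematopoietic, as clusters 1, 5, 10, 11, 18, 24, 28 and 38 lost their names and cluster 25 became pronephric-like. Without a minimum score, which names cluster 30 (46, 143 and 52 cells in sets 1, 2 and 3), they were 12.9% neutrophil-like, 13.4% unnamed and 67.1% all hematopoietic.

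With at least 1000 UMIs per cell the shares that moved were 28.7% erythroid-like, 10.6% progenitor-like, 2.01% mesenchymal-like, 0.852% mucus-secreting-like, 2.13% neural progenitor-like, 7.29% neuronal-like, 0.381% endothelial-like and 68.2% all hematopoietic. Without a filter on cells they were 25.2% erythroid-like, 12.5% progenitor-like, 0.867% intestinal-like, 6.21% lymphoid-like, 1.69% mesenchymal-like, 2.16% neural progenitor-like, 1.1% thrombocyte-like, 17.5% unnamed and 62.1% all hematopoietic. At Leiden resolution 0.5 they were 25.4% erythroid-like, 13.3% progenitor-like, 2.17% neural progenitor-like, 9.29% neuronal-like, 13.5% unnamed and 67.0% all hematopoietic, and at resolution 2 25% erythroid-like, 13.7% progenitor-like, 1.52% mesenchymal-like, 1.83% thrombocyte-like, 14.9% unnamed and 65.0% all hematopoietic. With doublets kept they were 12% progenitor-like, 1.66% mesenchymal-like, 2.19% neural progenitor-like, 9.17% neuronal-like, 13.6% unnamed and 67.0% all hematopoietic, and with the doublet limit of 0.2 26.0% erythroid-like, 12% progenitor-like, 6.83% lymphoid-like, 1.68% mesenchymal-like, 2.11% neural progenitor-like, 9.30% neuronal-like, 3.43% thrombocyte-like, 15.2% unnamed and 65.3% all hematopoietic. With each barcode set clustered on its own, they were 2.09% epidermal-like, 27.6% erythroid-like, 10.3% progenitor-like, 0.392% intestinal-like, 6.59% lymphoid-like, 1.45% mesenchymal-like, 0.106% mucus-secreting-like, 3.55% thrombocyte-like, 0.198% endothelial-like, 17.1% unnamed and 65.0% all hematopoietic. Among hematopoietic cells only, a smaller denominator gave 40.2% erythroid-like, 16.9% progenitor-like, 11.2% lymphoid-like, 7.93% macrophage-like, 18.1% neutrophil-like and 5.71% thrombocyte-like.

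The share of progenitor-like cells with G2/M transcripts was 78.0% with 1 UMI required, 73.9% after thinning to 2000 UMIs, 97.7% without thinning, 57.8% at Leiden resolution 2, 72.1% with the looser naming rule and 22.9% without hmgb2a and hmgb2b. Of genes with a leading class, macrophage-like cells led 1 in place of 2 by the share of cells after thinning, epidermal-like cells led 3 in place of 5 without barcode set 1, and intestinal-like cells led 1 in place of 2 without barcode set 2. By the share of cells after thinning, the leading class differed for kitlga, igf2a, notch2, il6st, fn1b, col1a1b, tnc and timp2a.

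List medians that moved were, under TMM scaling, 0.047 for oxidative phosphorylation in progenitor-like cells, 0.54 for S phase in thrombocyte-like cells, 1.23 for G2/M phase in thrombocyte-like cells, 0.62 for ribosome biogenesis in erythroid-like cells and 0.39 for dissociation stress in endothelial-like cells. With totals without globin, mitochondrial and ribosomal protein genes they were −2.00 for ribosome biogenesis in neutrophil-like cells and 0.70 for ribosome biogenesis in erythroid-like cells. With every cell weighted equally they were 0.30 for S phase in progenitor-like cells, 0.75 for S phase in thrombocyte-like cells and 0.36 for dissociation stress in endothelial-like cells. After subtraction of the library profile, at shares of 10.8%, 7.18% and 5.93% in sets 1, 2 and 3, which come from all globin counts outside erythroid-like and progenitor-like cells and are too high for free RNA where a few globin-rich cells carry them, it was −1.61 for ribosome biogenesis in neutrophil-like cells. With the looser rule they were 0.41 for S phase in progenitor-like cells and 0.41 for G2/M phase in progenitor-like cells. At Leiden resolution 2, G2/M turned to −0.26 in progenitor-like and 0.13 in lymphoid-like cells, and the medians that moved were 0.42 for S phase and 1.40 for ribosome biogenesis in progenitor-like, 0.22 for S phase in thrombocyte-like and −0.25 for S phase in lymphoid-like cells. Without a filter on cells, S phase turned to −0.57 in thrombocyte-like cells, and the medians that moved were 0.58 for S phase and 1.32 for ribosome biogenesis in progenitor-like, 0.93 for G2/M in thrombocyte-like, 0.40 for stress in macrophage-like, −1.14 for ribosome biogenesis in neutrophil-like, −0.54 for S phase in lymphoid-like and 0.27 for ribosome biogenesis in erythroid-like cells. With the thrombocyte-like class as cluster 29 alone, S phase turned to −1.03 and G2/M to −0.68; as cluster 13 alone, G2/M was 1.79. The cause of these turns was not tested, except that a single cluster leaves out the other. Cells of at least 1000 UMIs and members with at least 50 UMIs moved none of the 20 medians. Scaling moved the median gene too: under TMM it went from −0.42 to 0.04 in erythroid-like, from −0.32 to −0.12 in neutrophil-like from 0.18 to −0.28 in thrombocyte-like, from −0.10 to −0.20 in macrophage-like and from −0.19 to −0.36 in endothelial-like cells. Depth limits endothelial-like and neuronal-like cells, with medians of 1580 and 1842 counts per cell; thinning to 1000 UMIs kept 105 of 125 and 2079 of 2680 of them.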

Other observations

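Erythroid-like clusters, which were formed on the same genes, differed in globin and heme synthesis genes. Globin genes summed to 1588 and 3798 CPM in clusters 5 and 10, to 17868 CPM in cluster 24, to 177915 CPM in cluster 2 and to 716518 CPM in cluster 3. The heme synthesis gene cpox had 29.8, 57.8, 118 and 374 CPM in clusters 5, 10, 24 and 2, and 23.3 CPM in cluster 3. The gene of the first heme enzyme of red cells, alas2, had 256 CPM in cluster 2 and 1380 CPM in cluster 3. Ribosome biogenesis genes summed to 7033 CPM in cluster 5, 3815 CPM in cluster 2 and 188 CPM in cluster 3. The share of cells with at least 2 G2/M UMIs was 31.1% in cluster 5, 82.7% in cluster 10, 40.9% in cluster 24, 76.4% in cluster 2 and 1.99% in cluster 3. Globins take most counts of cluster 3. Without globin counts, a comparison chosen after the data were seen, these shares were 31.9%, 80.4%, 40.4%, 82.5% and 13.8% (12.3 to 15.5). Ribosome biogenesis genes then summed to 7047, 7829 and 5479 CPM in clusters 5, 10 and 24, and to 4783 and 822 CPM in clusters 2 and 3. The remaining erythroid-like cluster 38, with 72 cells, had a share of 60.3% and 6086 CPM without globin counts.

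Interleukin genes marked 2 kinds of blood cell. The type 2 cytokine gene il13 had 1332 CPM in cluster 27, a lymphoid-like cluster of 306 cells, and 0.670 CPM in cluster 4, the other lymphoid-like cluster. In cluster 27, il4 had 853 CPM and gata3, a transcription factor of helper and innate lymphoid cells, had 202 CPM. Neutrophil-like cells also carried il4, with 623 CPM (615 to 632) over the class and 1295 CPM in cluster 8. The mast or eosinophil marker cpa5 was among the leading genes of cluster 8 and of every other neutrophil-like cluster. Only 3 of 5 mast or eosinophil markers were measured, and a name needed 3 detected, so such cells may be hidden in this class. Both interleukin genes were chosen after their values were seen.

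Of the tests below, those on the globin genes, the number of genes per cell and the depth of set 1 were chosen after the results they measure had been seen in part. No biological explanation was tested in this part, because the labels tie no barcode set to an age.

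Globin transcripts were found in every class, with 12838 CPM in endothelial-like and 7017 CPM in neuronal-like cells. For the class sums, free RNA alone was argued against, since it reaches the droplets of a set alike, whereas highest and lowest class outside blood differed in every set, by a ratio of 20.1 in CPM where it was smallest and by more in the mean per cell. A few cells carried these sums, as 95.7% of the globin UMIs of epidermal-like cells of set 1 lay in 5% of the cells; in the median cell the ratio was 2, 1.67 and 1.67 in sets 1, 2 and 3, neither under 1.5 in every set nor above 3, so free RNA in the typical cell stays open. The ratio of hbae3 to hbbe1.1 followed the erythroid-like cells of the same set, with a median absolute log2 difference of 0.178 over the classes outside blood, although −1.30 was found in epidermal-like cells of set 3. Red cells or their RNA may be the source, but that ratio does not separate free RNA from red cells that share a droplet, are attached or are engulfed.

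Endothelial-like cells were few, although the sort described for the 2 samples had included them. If they had been placed in other clusters, cells outside the class with at least 3 of 10 endothelial genes would be as many as inside it, but 5 were found outside against 64 inside. That test sees only deep cells, as 64 of the 125 class members reach 3 genes, so shallow endothelial cells elsewhere could be missed. Loss at the lower limit of genes per cell is a possible explanation: 47.2% (38.2 to 56.3) of endothelial-like cells had fewer genes than 1.5 times the lowest number in their set, against 26.4% of other cells outside blood. Shallow cells were not few in every class, however. Neuronal-like cluster 9 held 1374 cells at a median of 1164 counts, against 1580 counts in endothelial-like cells. How many cells of either class fell below the limit is not known, so this comparison cannot decide. Cells lost before sequencing cannot be seen here.

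The il13-carrying cluster 27 had 4, 135 and 167 cells in sets 1, 2 and 3. Placement of such cells in other clusters of set 1 was argued against by 0 of 8388 kept cells of that set with at least 2 il13 UMIs, which allows a share of such cells of up to 0.044%, against 0.758% and 1.28% in sets 2 and 3. The limit is for cells with 2 UMIs and not for all cells expressing il13, as 75 of the 135 and 102 of the 167 cells of cluster 27 reached 2 UMIs in sets 2 and 3. Lower depth was argued against as well, since lymphoid-like cells of set 1 had a median of 7990 counts, above the 5624 of set 3. A difference between libraries, in the sort or in the age of the fish stays open and was not tested.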
